A study of Mus musculus with 6 samples.

How the data were processed

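Colonic crypts of Lgr5-lacZ male mice were profiled on 6 Affymetrix arrays, 2 each for control, DSS and tumor crypts, with biotin-labelled cRNA made from RNA of pooled tissue. The deposited values were MAS5 signal intensities per probe set on a linear scale, and per the labels MAS5 was the processing tool, with a version not given in the sources used here. On each array as deposited, the trimmed mean was near 500.2 with the highest and lowest 2% of probe sets left out, as computed from the values, which is the form that MAS5 scaling takes. No detection calls were in the table, and no raw array files were analysed here. The arrays' number limits the precision, and probe sets near the floor carry background signal.

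The table held 22690 probe sets, of which 64 controls were set aside. Of the remaining 22626, 20380 mapped to 1 gene symbol, 691 to several and 1555 to none, and 99.9% of the first had their gene identifier in the reference table. Values were transformed as log2 of the intensity plus 17.8, the 25th percentile of all values. Probe sets above their array's median on at least 2 arrays were kept (12146), and for each gene the probe set with the highest mean was tested, which gave 7456 genes. No further normalization was applied. The fixed genes Muc2, with no probe set for it alone, and Col1a1, below the filter with mean intensities of 28.1 and 51.2 in control and 49.8 and 137.5 in tumor crypts on its 2 probe sets, were not tested.

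All 3 groups were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, and the 3 differences between groups were tested with Benjamini-Hochberg adjustment and a threshold of 0.05. Tests were 2-sided. Gene lists (39, with 792 genes, of which 790 matched a gene identifier and 526 were tested) were fixed before the data were examined, as were the groups, the comparisons, the named genes' rule and most alternatives. The 34 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry's directional p. T and NK cell, B and plasma cell, neutrophil, enteric neuron and glia, and tuft cell lists had fewer and were not tested. Named genes were the 8 largest rises and falls among called genes whose groups did not overlap, or the 4 of smallest p per direction where none was called. To them came up to 3 members of smallest p from each list that passed or held 3 called genes, and 13 fixed genes. Genes named outside this rule are said to be chosen after their values were seen.

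The pipeline was tested on simulated data, with 20 simulations of 200 changed genes among 7456. In DSS against control, 68.1% of changes of 1 and 98% of changes of 2 on the log2 scale were recovered, with 11.6 false calls on average. These shares hold for 200 changed genes on independent arrays, since the adjustment over all genes is stricter when fewer genes change. They do not give the power of the real DSS comparison, where Atf3 at 1.64 and Hbegf at 1.43 did not pass. Lists shifted by 0.5 were recovered in 100% of cases by camera with the preset correlation, in 0% with an estimated correlation and in 35% by fry. The simulated genes and arrays were independent, a setting that suits a preset correlation near 0. These shares therefore cannot tell which list test is right for the real arrays. Alternatives covered quantile normalization, median centring, the pseudocount, the filter, the handling of probe sets, the intensity trend, fits of 2 groups only, the replicate number as a block, and each array left out in turn. A block for the arrays with high poly-A controls was added after the data were seen, as was a 2-group fit with the replicate number as a block. Groups of 2 arrays are too small for an outlier test or for counts over other splits of the samples. Correlation between DSS and tumor changes was compared with 100 simulations of unchanged groups around shared controls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.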

Results

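Messenger RNA of mouse colonic crypts, the epithelial glands that line the colon, was measured on Affymetrix expression arrays in 3 groups of 2 arrays. Each array carried a pool from 2 male Lgr5-lacZ mice, which bear a lacZ reporter at the gene of the stem cell receptor Lgr5, and the labels call the pools of a group independent biological replicates. The labels give an age of 6 to 8 weeks for all groups. Control crypts came from untreated mice, DSS crypts from mice on day 2 of 1% dextran sulfate sodium, and tumor crypts from 12 pooled adenomas per array. The adenomas arose after azoxymethane, a colon carcinogen given at 12.5 mg per kg, and DSS cycles of 2, 1.5 and 1.0%, and were collected 90 days after azoxymethane. Median intensities of the arrays lay between 94.8 in DSS replicate 1 and 131 in tumor replicate 2, and the number of arrays, 2 per group, limits the precision. Across the 7456 genes tested, which are not independent replicates, Pearson's r between log2 intensities was 0.971 for the control arrays, 0.978 for the DSS arrays and 0.959 for the tumor arrays. It was 0.983 between control and DSS replicate 1, 0.986 between control and DSS replicate 2, and 0.809 to 0.876 between a tumor array and any array of the other groups. Poly-A control transcripts, which are spiked into the RNA, had mean intensities of 420.3 on control replicate 1 and 638 on DSS replicate 1, against 164 to 208 on the other 4 arrays. The log2 ratio of 3' to 5' probe sets, a sign of RNA quality, was 0.95 and 1.04 for actin on the tumor arrays and 1.20 to 1.63 on the others, and -0.05 and 0.04 for Gapdh against 0.07 to 0.23, so both tumor arrays lay below the other 4. Group changes of gene lists are also given between arrays of the same number. Lists given with an adjusted p from camera with an estimated correlation were called by camera with a preset one. The estimated form recovered 0 to 5% of simulated list shifts, so its high p-values say little either way. Genes were independent in those simulations, so these cannot show that the preset calls are right.

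The first comparison set DSS crypts against control crypts, for the early response of the crypt to a polysaccharide that injures the colonic epithelium. Immediate early genes, which are transcribed soon after a stimulus without new protein synthesis, rose as a group: 16 of the 18 measured were higher in DSS crypts, with a median log2 change of 0.78 (adjusted p = 0.582 with an estimated correlation). Atf3, a stress-induced transcription factor, had intensities of 874 ± 213 in control and 2746 ± 518 in DSS crypts (mean ± SD, n = 2 and 2). Ier2 had values of 2990.0 ± 133 and 5426 ± 290.2, and the antiproliferative gene Btg2 of 3253 ± 94.4 and 5730.4 ± 139. Crypt base stem cell genes fell as a group, with all but 2 of 14 lower and a median of -0.43 (adjusted p = 0.401 with an estimated correlation). Ascl2, a transcription factor of intestinal stem cells, measured 208 ± 18.1 in control and 83.4 ± 2.87 in DSS crypts. Lgr5 measured 85.2 ± 17.9 and 33.7 ± 20.4, and the cell cycle regulator Rgcc 571 ± 30.2 and 211 ± 71.6. Lgr5 lay below the array median on each control and DSS array, so it passed the filter only through the tumor arrays. Its log2 change of -1.05 became -1.43 with a pseudocount of 1 and -0.45 with one at the median of all values. DNA replication genes also fell as a group, with all but 3 of 25 lower and a median of -0.45 (adjusted p = 0.401 with an estimated correlation). Mcm6, a subunit of the replicative helicase, measured 728 ± 67.3 and 347 ± 101, and Mcm7 1253 ± 196 and 799 ± 53.3. By contrast, Mcm2 had a log2 change of 0.91 ± 0.30 (SE) on its tested probe set and -0.77 on its other one. Mitosis genes did not pass, with a median of 0.03 over 27 genes. The proliferation marker Mki67 measured 1042 ± 40.7 and 1098 ± 193. Crypt base genes, whose median moved by more than 1.5 times in some settings, had a median of -0.26 without DSS replicate 1. DNA replication genes had a median of -0.27 with a pseudocount at the median.

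Ribosome biogenesis genes fell as a group in DSS crypts, with a median of -0.24 over 23 genes (adjusted p = 0.582 with an estimated correlation). The nucleolar genes Gnl3 and Nop56 had log2 changes of -0.64 ± 0.16 and -0.58 ± 0.19. Wnt target genes fell as a group, with a median of -0.13 over 25 (adjusted p = 0.72 with an estimated correlation). Their feedback regulator Axin2 had a change of -0.79 ± 0.22 on its tested probe set and -0.01 on the other. Genes of the unfolded protein response fell as a group, with a median of -0.22 over 20 (adjusted p = 0.791 with an estimated correlation). One of them, the endoplasmic reticulum chaperone Hsp90b1, was at -0.43 ± 0.16. Rises were found for enteroendocrine genes (median 0.24, n = 11 genes, adjusted p = 0.796 with an estimated correlation) and for cholesterol synthesis genes (median 0.17, n = 17 genes, adjusted p = 0.837 with an estimated correlation). The gut hormone Pyy changed by 0.41 ± 0.17 and squalene synthase, Fdft1, by 0.39 ± 0.20. Targets of YAP, a transcriptional coactivator in regenerating epithelium, passed with a median of 0.05 and a mean of 0.16 over 14 genes (adjusted p = 0.582 with an estimated correlation). Their growth factor Hbegf, a ligand of the EGF receptor, measured 497 ± 38.5 in control and 1369 ± 86.3 in DSS crypts, a log2 change of 1.43 ± 0.17. Fibroblast genes, markers of another cell type, passed with 19 of 19 higher and a median of 0.38 (adjusted p = 0.856 with an estimated correlation). Pan-epithelial genes had a median of 0.09 and Epcam, an epithelial adhesion gene, of 0.09. Among other fixed genes, the antimicrobial lectin Reg3b measured 8.79 ± 11.4 and 118 ± 120.1, and Reg3g 4.21 ± 0.953 and 21.2 ± 26.2. The leukocyte gene Ptprc measured 186 ± 29.5 and 154 ± 101, and the differentiation keratin Krt20 4574 ± 1018 and 2665 ± 219. The log2 changes of the iron-binding gene Lcn2 and the carbonic anhydrase Car1 were 0.01 and -0.03. Outside the lists, the genes of smallest p were Klf10 at 0.98 ± 0.16, Hells, a chromatin remodeler, at -1.01 ± 0.17 and the efflux pump Abcg2 at -0.98 ± 0.18. Wnt target genes, whose median moved by more than 1.5 times in some settings, had medians of -0.20 without DSS replicate 1 and -0.33 without tumor replicate 1 and without tumor replicate 2. No tumor array enters a DSS minus control change, so the -0.33 reflects which genes were tested. Mmp7 (33.6 in control, 30.2 in DSS), Apcdd1 (10.1, 18.4) and Wif1 (28.4, 24.4) passed the filter only through the tumor arrays. Such genes near background are part of the -0.13. Enteroendocrine genes had medians of 0.45 without control replicate 2 and 0.37 without DSS replicate 1. YAP target genes had medians of 0.35 with the 75th percentile filter, 0.25 without control replicate 2, 0.02 without DSS replicate 1 and 0.11 without tumor replicate 1 and without tumor replicate 2. As for Wnt targets, the 0.11 reflects which genes were tested. Unfolded protein response genes had a median of -0.37 without control replicate 2. Fibroblast genes had medians of 0.24 with a pseudocount at the median, 0.75 without control replicate 2 and 0.74 without DSS replicate 1. Ribosome biogenesis genes had a median of -0.48 without control replicate 2. Cholesterol synthesis genes had medians of 0.45 without control replicate 1 and 0.37 without DSS replicate 2. The list call ended for enteroendocrine genes at a median of 0.15 without the filter. It ended for YAP target genes at 0.03 with quantile normalization, 0.09 without the filter and 0.05 without an intensity trend. It ended for fibroblast genes at 0.32 without the filter and 0.35 with the 75th percentile filter. It ended for cholesterol synthesis genes at 0.17 without the filter and without an intensity trend.

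No single gene passed in DSS crypts in the fit of all 3 groups: limma called 0 of 7456 genes, the smallest adjusted p was 0.198 for Hbegf, and 189 genes had an unadjusted p under 0.05 (79 higher, 110 lower), where 372.8 would be expected by chance. The groups did not overlap in 1975 genes, or 26.5%, where chance gives 33.3%. These chance values are for independent arrays, whereas control and DSS arrays of the same number had higher r (0.983 and 0.986) than the arrays of a group (0.971 and 0.978). Variation shared by same-numbered arrays adds to the error of this fit and can lower both counts. A 2-group fit with the replicate number as a block, added after the data were seen, called 124 genes, with 569 at an unadjusted p under 0.05. It has 1 residual degree of freedom and rests on pooled variances, and the 3-group fit with that block called 0. When p-values were adjusted over the list alone, 8 immediate early genes were higher and 5 crypt base genes lower (Rgcc, Ascl2, Cdca7, Lgr5 and Axin2), against 0 over all genes tested. Of these, Lgr5 passed the filter only through the tumor arrays. The same adjustment called 3 colonocyte genes lower, namely Krt20 and, chosen after their values were seen, Tmigd1 at -1.79 and Emp1 at -1.44. It called 1 gene each for Wnt targets (Ascl2), YAP targets (Hbegf), p53 targets (Btg2) and, chosen after their values were seen, heat shock genes (Dnajb1, 0.81), antimicrobial genes (Slpi, 1.77) and ion transport genes (Scnn1g, -1.50). Of the 34 lists tested, camera with a preset correlation called 10 (5 higher, 5 lower), camera with an estimated correlation 0 and fry 0. Between arrays of the same number, the median change of the immediate early list was 0.74 between the arrays numbered 1 and 0.86 between those numbered 2, that of the crypt base list -0.63 and -0.29, and that of the DNA replication list -0.51 and -0.29. These 3 lists kept their calls whichever array was left out. Without control replicate 1, calls ended for Wnt targets (median -0.05), ribosome biogenesis (-0.06), the unfolded protein response (0.07), enteroendocrine (0.00), YAP target (-0.06) and fibroblast genes (-0.000482). Calls also ended without DSS replicate 2 for the unfolded protein response (-0.13), enteroendocrine (0.13), YAP target (0.04) and fibroblast genes (0.04), and for cholesterol synthesis without control replicate 2 (-0.06) or DSS replicate 1 (-0.07). Lists not called with all arrays could pass camera with an array left out, namely pan-epithelial genes, higher without control replicate 1 (0.18) or DSS replicate 2 (0.21), and p53 targets, higher without control replicate 2 (0.19) or DSS replicate 1 (0.12). So could antimicrobial genes, higher without DSS replicate 2 (0.10), heat shock genes, lower without control replicate 2 (-0.39), and colonocyte genes, lower without DSS replicate 2 (-0.06). Ion transport genes were called lower without DSS replicate 2 (-0.22), tumor replicate 1 or tumor replicate 2 (-0.21 each). With all arrays but other settings, camera also called colonocyte genes at -0.09 with quantile normalization, -0.10 with median centring, -0.08 with a pseudocount at the median and -0.11 with the 75th percentile filter. Antimicrobial genes passed it at 0.17 with median centring. Targets of p53 passed it at 0.12 with median centring. Pan-epithelial genes passed it at 0.10 with the 75th percentile filter. Ion transport genes passed it at -0.22 with median centring and -0.21 with the 2 compared groups alone in the fit.

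**Figure D1:**
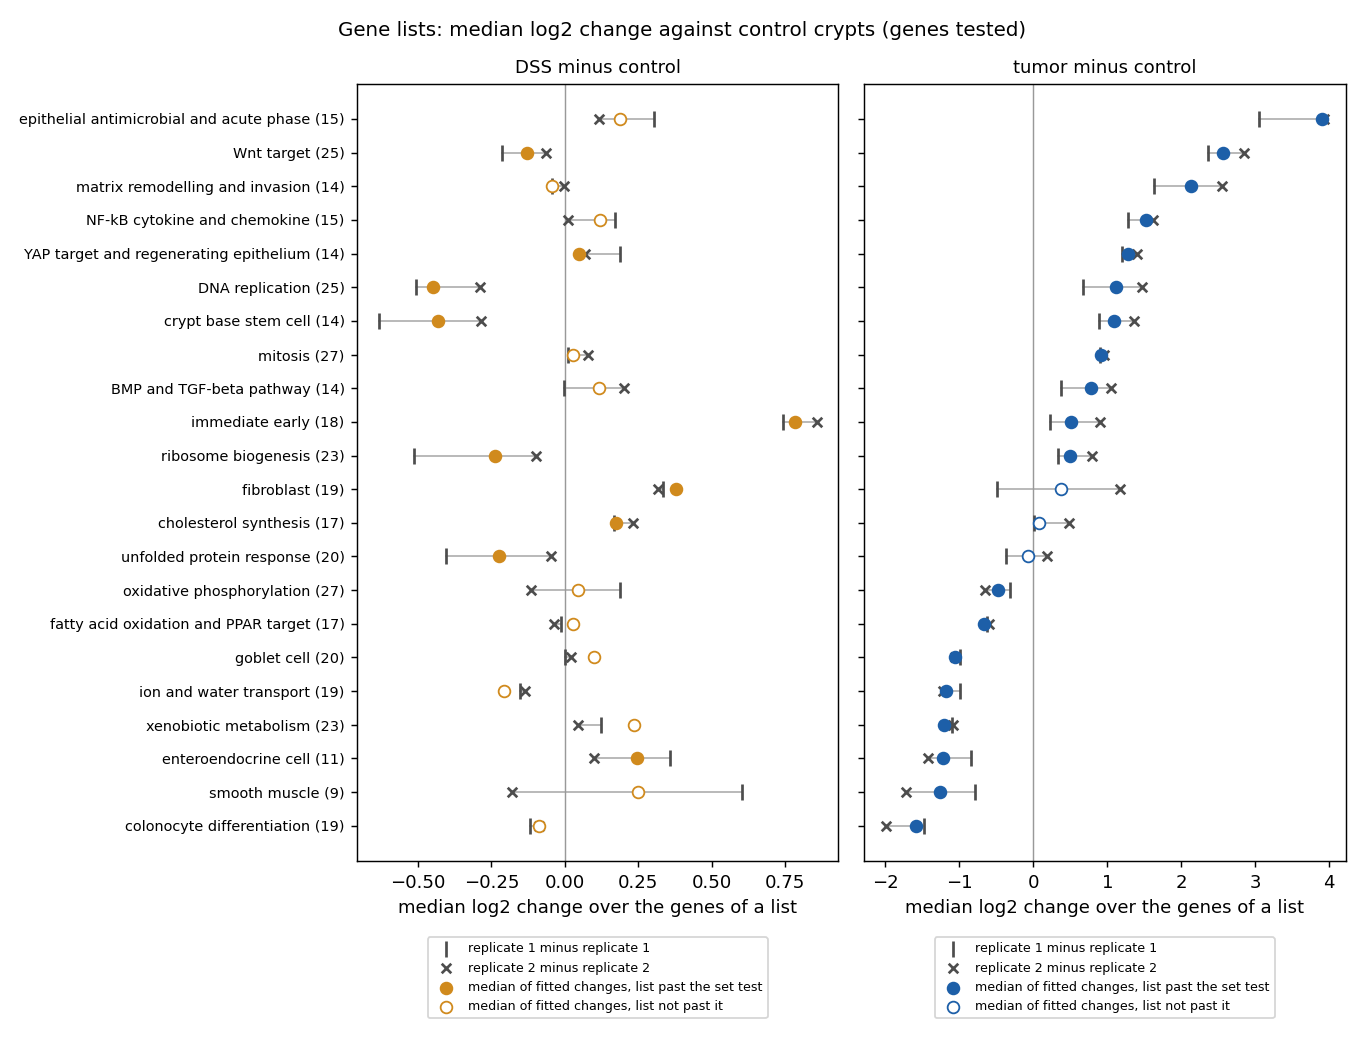
Median log2 change of gene lists in DSS crypts (left) and tumor crypts (right) against control crypts, on separate horizontal scales, with the number of genes tested in brackets. Filled points passed camera with a preset correlation and open points did not, and bars and crosses mark the medians between same-numbered arrays; immediate early genes stood at 0.78 in DSS crypts, and Wnt target genes at 2.56 in tumor crypts.

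The second comparison set tumor crypts against control crypts, for the expression program of the adenomas. Wnt target genes rose, 22 of 25 past the test with a median log2 change of 2.56 (adjusted p = 0.219 with an estimated correlation). Mmp7, a matrix metalloproteinase, rose from 33.6 ± 3.84 to 5996 ± 406 (mean ± SD, n = 2 and 2), a log2 change of 6.87 ± 0.20 (SE, adjusted p = 1.66e-06). The Wnt inhibitors Apcdd1 and Wif1 rose by 7.47 ± 0.29 and 6.62 ± 0.24. Apcdd1 had a control mean of 10.1, below the added pseudocount, and its change was 9.04 and 5.39 with a pseudocount of 1 and with one at the median of all values. Axin2 rose by 2.56 ± 0.22 on its tested probe set, with a change of 1.12 on the other. Crypt base stem cell genes rose in 8 of 14 cases, with a median of 1.09 (adjusted p = 0.278 with an estimated correlation). Lgr5 rose from 85.2 ± 17.9 to 549.6 ± 52.4, a log2 change of 2.47 ± 0.32 (adjusted p = 0.0015). Ascl2 rose from 208 ± 18.1 to 489 ± 13.5, by 1.17 ± 0.20 (adjusted p = 0.00456). The matricellular gene Smoc2 rose by 2.04 ± 0.22 and the receptor Tnfrsf19 by 4.67 ± 0.40, the latter 6.81 and 2.55 with those pseudocounts. Other probe sets of these genes gave 0.48 for Smoc2 and 0.16 to 1.68 for Tnfrsf19. Aqp4, chosen after its values were seen, fell by 1.45. Of 5 reserve stem cell genes 3 rose (Clu, Hopx and Bmi1), led by the secreted chaperone Clu at 3.41 ± 0.23, and the list passed fry (median 0.71, adjusted p = 0.00886) but not camera. Single-gene calls ended with each array centred on its median for Hopx (0.46) and Bmi1 (0.56) (log2 changes). They ended for Hopx (0.67) and Bmi1 (0.65) without control replicate 1. They ended for Hopx (0.74) without control replicate 2. They ended for Hopx (0.60) and Bmi1 (0.76) without tumor replicate 1. They ended for Bmi1 (0.86) without tumor replicate 2. Crypt base genes, whose median moved by more than 1.5 times in some settings, had a median of 0.71 without tumor replicate 2. Wnt target genes had medians of 1.39 without tumor replicate 1 and 1.25 without tumor replicate 2. As the mean over probe sets, the log2 change of Smoc2 was 1.26.

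Proliferation genes were higher in tumor crypts. DNA replication genes rose in 19 of 25 cases (median 1.12, adjusted p = 0.219 with an estimated correlation). Among them were the ribonucleotide reductase subunit Rrm2 at 2.33 ± 0.27, Gins1 at 1.59 ± 0.20 and Mcm7 at 1.27 ± 0.19. Mitosis genes rose in 19 of 27 cases (median 0.92, adjusted p = 0.107 with an estimated correlation). They included the spindle checkpoint gene Mad2l1 at 1.41 ± 0.18, Ube2c at 1.09 ± 0.18 and topoisomerase Top2a at 1.47 ± 0.16, the last with -0.09 on its other probe set. Mki67 measured 1042 ± 40.7 in control and 1692 ± 485 in tumor crypts and did not pass (adjusted p = 0.0721). Ribosome biogenesis genes rose as a group (median 0.50, adjusted p = 0.505 with an estimated correlation). Of 23 such genes 5 passed, namely Nop56, Ddx21, Nop2, Mybbp1a and Pes1 (the last pair chosen after their values were seen). The nucleolar gene Nop56 changed by 1.03 ± 0.19. Single-gene calls ended without tumor replicate 2 for Nop2 (0.87) and Mybbp1a (0.84) (log2 changes). They ended for Mybbp1a (0.69) and Pes1 (0.49) with each array centred on its median. They ended for Mybbp1a (0.73) and Pes1 (0.62) without control replicate 2. They ended for Pes1 (0.64) without tumor replicate 1. Mki67 passed without tumor replicate 1 (0.95). Ribosome biogenesis genes, whose median moved by more than 1.5 times in some settings, had medians of 0.25 with median centring, 0.77 without control replicate 1 and 0.29 without control replicate 2.

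Antimicrobial and acute phase genes rose in 10 of 15 cases in tumor crypts, with a median of 3.90 (adjusted p = 0.219 with an estimated correlation). The serum amyloid genes Saa1 and Saa2, chosen after their values were seen, fell by 0.83 and 1.02. Reg3b rose from 8.79 ± 11.4 to 11417 ± 6159, a log2 change of 8.71 ± 0.66 (adjusted p = 0.000143), and Reg3g by 7.81 ± 0.47. Rises were also seen in the calcium-binding neutrophil gene S100a8 at 6.43 ± 0.88, Lcn2 at 6.13 ± 0.54 and the secreted phospholipase Pla2g2a at 4.93 ± 0.27. Cytokine and chemokine genes of the NF-kB list rose in 9 of 15 cases (median 1.52, adjusted p = 0.463 with an estimated correlation). Their risers included the neutrophil attractants Cxcl5 at 7.51 ± 0.34 and Cxcl1 at 4.40 ± 0.51 and the alarmin Il33 at 2.70 ± 0.27. Control means of Reg3b, Reg3g, S100a8, Lcn2 and Cxcl5 lay below the 17.8 added before the log, so the size and order of these changes depend on that pseudocount. With a pseudocount of 1 and with one at the median of all values, the log2 change was 8.55 and 6.52 for Reg3b, 9.89 and 5.49 for Reg3g, 8.61 and 4.33 for S100a8, 7.27 and 4.27 for Lcn2 and 10.06 and 5.16 for Cxcl5. Ccl28, chosen after its values were seen, fell by 1.44. Matrix remodelling genes rose in 11 of 14 cases (median 2.13, adjusted p = 0.301 with an estimated correlation). Examples were the plasminogen activator Plat at 5.59 ± 0.34 and the hyaluronan receptor Cd44 at 2.76 ± 0.24. YAP target genes rose in 8 of 14 cases (median 1.28, adjusted p = 0.219 with an estimated correlation). The scaffold gene Ajuba rose by 3.16 ± 0.37, and Anxa3, chosen after its values were seen, fell by 0.71. Genes of the BMP and TGF-beta pathway rose in 6 of 14 cases (median 0.78, adjusted p = 0.463 with an estimated correlation). The pseudoreceptor Bambi rose by 2.07 ± 0.27 and the activin subunit Inhbb by 3.15 ± 0.50, against -0.12 on its other probe set. Inhbb, with a control mean of 11.5, changed by 4.99 and 1.51 with those pseudocounts. Bmp2, chosen after its values were seen, fell by 1.08. Immediate early genes rose in 6 of 18 cases (median 0.51, adjusted p = 0.715 with an estimated correlation). Ier3 rose by 3.53 ± 0.26 and Socs3, a feedback inhibitor of cytokine signalling, by 2.89 ± 0.46, and Klf4 fell by 1.01 ± 0.17. Outside the lists, Mt4, a metallothionein, rose from 63.1 ± 5.89 to 7094 ± 691, a log2 change of 6.46 ± 0.18. Single-gene calls ended without control replicate 2 for Saa1 (-0.74), Saa2 (-0.72) and Anxa3 (-0.61) (log2 changes). They ended for Saa2 (-0.77) and Bmp2 (-0.73) without tumor replicate 1. They ended for Anxa3 (-0.60) without tumor replicate 2. They ended for Bmp2 (-0.72) without control replicate 1. NF-kB genes, whose median moved by more than 1.5 times in some settings, had a median of 0.96 with a pseudocount at the median. Without tumor replicate 1 or 2 it was 0.53 or 0.0075, and that of antimicrobial genes 0.25 or 0.52. Genes high in tumor alone, such as Reg3g and Cxcl5, then left the test, so these medians cover fewer genes. YAP target genes had medians of 0.83 without the filter, with the 75th percentile filter and without tumor replicate 1 and 0.84 without tumor replicate 2. Immediate early genes had medians of 0.26 with median centring and 1.14 without tumor replicate 1. Matrix remodelling genes had medians of 1.24 with a pseudocount at the median, 1.12 without tumor replicate 1 and 0.72 without tumor replicate 2. The list call ended for BMP and TGF-beta genes at a median of 0.94 with the 75th percentile filter and 0.78 without an intensity trend. With a pseudocount at the median, log2 changes were -0.93 for Ccl28 and 1.95 for Ajuba. Calls of Saa2 and Bmp2 also ended without the filter. Without an intensity trend calls ended for Bmp2. Inhbb was at -0.12 without the filter, where another probe set is used.

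Genes of differentiated colon cells fell in tumor crypts. Colonocyte genes fell in 12 of 19 cases, with a median of -1.58 (adjusted p = 0.107 with an estimated correlation). Car4, a membrane carbonic anhydrase, fell from 6019 ± 1082 to 181 ± 154, a log2 change of -5.17 ± 0.51 (adjusted p = 0.000437). The water channel Aqp8 changed by -4.90 ± 0.36, the chloride exchanger Slc26a3 by -4.06 ± 0.35, the protease Mep1a by -2.64 ± 0.23 and Car1 by -1.80 ± 0.28. Krt20 measured 4574 ± 1018 and 3548 ± 169 and did not pass. Ion and water transport genes fell in 12 of 19 cases (median -1.17, adjusted p = 0.107 with an estimated correlation). Examples were the sulfate transporter Slc26a2 at -2.48 ± 0.17 and the butyrate transporter Slc5a8 at -2.07 ± 0.14. Goblet cell genes fell in 13 of 20 cases (median -1.05, adjusted p = 0.219 with an estimated correlation). The mucus protein gene Clca1 fell from 11943 ± 565 to 1042 ± 386, a log2 change of -3.54 ± 0.23, and Atoh1, the transcription factor of secretory cells, fell by 1.67 ± 0.22. Enteroendocrine genes fell in 7 of 11 cases (median -1.21, adjusted p = 0.467 with an estimated correlation). They included the hormone genes Gcg at -3.20 ± 0.22 and Insl5 at -3.78 ± 0.33, whereas the transcription factor Isl1 rose by 2.44 ± 0.22. Xenobiotic metabolism genes fell in 15 of 23 cases (median -1.21, adjusted p = 0.267 with an estimated correlation). Among them were the efflux pump Abcb1a at -2.64 ± 0.17 and the cytochrome Cyp3a13 at -2.58 ± 0.23. In this list 3 genes rose, namely Cyp2b10, Gsta4 and Txnrd1, chosen after their values were seen. Fatty acid oxidation and PPAR target genes fell in 10 of 17 cases (median -0.66, adjusted p = 0.219 with an estimated correlation). The thiolase Acaa2 was at -1.23 ± 0.20, while Pdk4, an inhibitor of pyruvate oxidation, rose by 2.64 ± 0.43. Oxidative phosphorylation genes fell in 9 of 27 cases (median -0.48, adjusted p = 0.50 with an estimated correlation). One was the complex II subunit Sdhb at -0.84 ± 0.21. Outside the lists, the largest falls past the test were in the pentraxin Mptx1 (-4.66 ± 0.33), Rps4l (-4.21 ± 0.51), the dipeptidase Dpep1 (-4.03 ± 0.44), Slc37a2 (-3.89 ± 0.29) and Ogn (-3.82 ± 0.41), a matrix proteoglycan. Single-gene calls ended with each array centred on its median for Gsta4 (0.77) and Txnrd1 (0.60) (log2 changes). They ended for Gsta4 (0.95) and Sdhb (-0.95) without control replicate 1. They ended for Gsta4 (1.09), Txnrd1 (0.71) and Sdhb (-0.73) without control replicate 2. They ended for Gsta4 (0.70) without tumor replicate 1. They ended for Txnrd1 (0.64) and Sdhb (-0.56) without tumor replicate 2. Enteroendocrine genes, whose median moved by more than 1.5 times in some settings, had medians of -0.65 with a pseudocount at the median and -0.74 without the filter. Oxidative phosphorylation genes had a median of -0.73 with median centring. With a pseudocount at the median, log2 changes were 1.47 for Cyp2b10, 1.42 for Pdk4, -2.65 for Rps4l and -2.47 for Ogn. Calls of Sdhb also ended without the filter.

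Some marker lists moved unevenly between the tumor arrays and others did not. Of 19 fibroblast genes 4 rose, namely Mgp at 6.27 ± 0.62, the intermediate filament gene Vim at 3.25 ± 0.52, Fn1 at 2.34 ± 0.49 and Fbln1 at 1.97 ± 0.40. The list passed neither camera nor fry with all arrays, and its median was -0.48 between the arrays numbered 1 and 1.17 between those numbered 2. Interferon response genes had medians of -0.66 and 1.45 in the same pairs and MHC class II genes of -0.44 and 1.39. In these lists 2 (Usp18 and Ifit2) and 0 genes passed. Macrophage and dendritic cell genes had medians of 0.86 and 1.07 in these pairs and endothelial genes of 1.03 and 1.25, higher in both, and neither list passed camera or fry with all arrays. Camera called macrophage and dendritic cell genes higher without control replicate 2 (1.45) or tumor replicate 1 (1.45), and endothelial genes without DSS replicate 1 (1.25). It called interferon response genes higher without control replicate 1 (0.75) or tumor replicate 1 (0.93), MHC class II genes higher without tumor replicate 1 (1.77) and genes of the unfolded protein response lower without control replicate 2 (-0.31). Smooth muscle genes fell as a group (median -1.27, adjusted p = 0.64 with an estimated correlation) with 0 of 9 genes past the test. Of 10 macrophage genes Lyz2 and Cd14 rose and Ctss fell, of 5 endothelial genes Sox17 rose, and Ptprc had a log2 change of -0.03 ± 0.67. Of 18 pan-epithelial genes Cldn4 and Krt18 rose and Cdx1 and Hnf4a fell, around a median of -0.10. Epcam measured 12809 ± 179.5 and 12069.9 ± 1006. The remaining lists passed neither camera nor fry with all arrays: 4 of 21 p53 targets rose (Plk2, Phlda3, Ephx1 and Ddit4), 2 of 16 heat shock genes rose (Hspb1 and Hspb8) and 2 fell (Hspa1a and Hspa1b). In the Notch list Notch1 and Notch2 rose and Atoh1, Dll1 and Nrarp fell, and among distal colon genes Hoxa9 rose and Hoxb13 and Hoxa11os fell. Cldn4 rose and Cldn15 fell among 14 tight junction genes, Pkm rose among 18 hypoxia and glycolysis genes, Stard4 and Msmo1 fell among 17 cholesterol synthesis genes, and 0 of 20 genes of the unfolded protein response passed. Of these genes, Fn1, Usp18, Ifit2, Sox17, Ddit4, Hspa1a, Notch1, Notch2, Cldn15, Pkm, Stard4, Msmo1 and Hnf4a were chosen after their values were seen. Single-gene calls ended without control replicate 2 for Fn1 (2.32), Usp18 (1.33), Ifit2 (1.08), Cd14 (0.56), Krt18 (0.47), Ddit4 (1.12), Notch1 (1.11), Notch2 (1.23), Dll1 (-1.21), Hoxb13 (-0.73), Hoxa11os (-1.08), Cldn15 (-1.16), Pkm (0.91) and Msmo1 (-0.44) (log2 changes). They ended for Usp18 (1.40), Ifit2 (1.45), Cd14 (0.51), Krt18 (0.64), Cdx1 (-0.78), Hnf4a (-0.60), Ddit4 (1.57), Notch1 (0.69), Notch2 (1.005), Hoxb13 (-0.62), Hoxa11os (-1.003), Cldn15 (-0.62), Pkm (0.61), Stard4 (-0.64) and Msmo1 (-0.60) without tumor replicate 2. They ended for Cd14 (0.46), Krt18 (0.38), Hoxa9 (0.55) and Pkm (0.56) with each array centred on its median. They ended for Cd14 (0.85), Cdx1 (-0.56), Hnf4a (-0.47), Notch1 (1.27), Notch2 (1.56), Hoxb13 (-0.58), Cldn15 (-0.67), Pkm (0.70) and Stard4 (-0.58) without control replicate 1. They ended for Cd14 (0.70), Hnf4a (-0.74), Cldn15 (-0.92) and Msmo1 (-0.61) without DSS replicate 1. They ended for Cd14 (0.70) and Msmo1 (-0.61) without DSS replicate 2. They ended for Krt18 (0.62), Cdx1 (-0.83), Hnf4a (-0.87), Hoxb13 (-0.69) and Msmo1 (-0.62) without tumor replicate 1. Smooth muscle genes, whose median moved by more than 1.5 times in some settings, had medians of -0.73 with a pseudocount at the median, -2.55 without control replicate 1 and -2.30 with the arrays of high poly-A controls as a block. The list call ended for smooth muscle genes at a median of -0.83 without the filter and -1.05 with the 75th percentile filter. With a pseudocount at the median, log2 changes were 0.97 for Fbln1, 1.32 for Hspb8, 0.91 for Notch2 and -0.95 for Dll1. Calls of Usp18, Ifit2, Cd14, Hnf4a, Notch1, Notch2, Cldn15, Pkm and Msmo1 also ended without the filter. Without an intensity trend calls ended for Cd14, Hnf4a, Notch1, Cldn15, Pkm and Msmo1. With the 2 compared groups alone in the fit calls ended for Cd14, Hnf4a, Cldn15 and Msmo1. With quantile normalization calls ended for Hnf4a (-0.64). With all kept probe sets tested calls ended for Hnf4a. With all arrays but other settings, camera also called macrophage and dendritic cell genes at 0.62 with median centring and 0.88 without the filter. Endothelial genes passed it at 1.00 with median centring, 0.71 without the filter and 1.25 with the 2 compared groups alone in the fit. Cholesterol synthesis genes passed it at 0.37 with the arrays of high poly-A controls as a block.

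In all, limma called 1680 of 7456 genes in tumor crypts, 954 higher and 726 lower, of which 967 changed by at least 1 on the log2 scale. The groups did not overlap in 61.5% of genes against 33.3% by chance. Adjusted over the list alone, 23 Wnt targets, 24 mitosis, 20 DNA replication, 10 crypt base, 10 antimicrobial and 12 matrix remodelling genes were higher. Lower by that count were 14 colonocyte, 17 goblet cell, 13 ion transport, 15 xenobiotic and 20 oxidative phosphorylation genes. Camera with a preset correlation called 19 of 34 lists (11 higher, 8 lower), camera with an estimated correlation 0, and fry 16, of which 15 were also called with the preset and the other was the reserve stem cell list. With each array centred on its median, the median change of all genes moved from 0.05 to -0.20 and the split to 651 higher and 1227 lower. All 1680 genes kept their sign and 1364 their call. The count fell to 846 without control replicate 2 and to 702 without tumor replicate 2. Without a tumor array, genes high in tumor alone leave the test, since the filter needs 2 arrays. The antimicrobial call ended without tumor replicate 1 (median 0.25) or 2 (0.52), as did that of the NF-kB list (0.53 and 0.0075). The BMP (0.30) and immediate early (0.25) calls ended without tumor replicate 2. The smooth muscle call ended without control replicate 2 (-0.26), DSS replicate 2 (-1.05) or tumor replicate 1 (-0.59). The fibroblast list, not called with all arrays, had a median of 1.33 without tumor replicate 1 and -0.81 without tumor replicate 2, both past the test. Azoxymethane, the DSS cycles, the 90 days since azoxymethane and the adenoma itself differ together between these groups, as did the 3' to 5' ratios of actin and Gapdh. Age at collection may differ too. The labelled 6 to 8 weeks, the same for all groups, cannot be the age of tumor mice 90 days after azoxymethane.

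**Figure D2:**
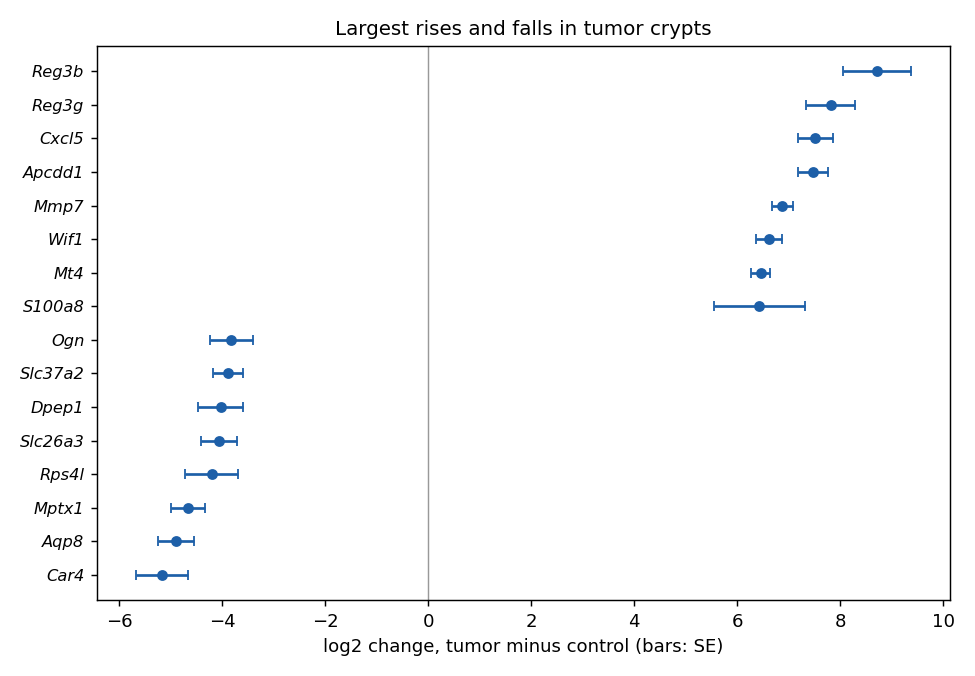
Log2 change in tumor minus control crypts, with SE as bars, of the 8 genes that rose most and the 8 that fell most among those past the limma test with groups that did not overlap. The range runs from -5.17 for Car4 to 8.71 for Reg3b, but the size and order of the rises depend on the pseudocount added before the log, below which the control means of Reg3b, Reg3g, Cxcl5, Apcdd1 and S100a8 lay.

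The third comparison set tumor crypts against DSS crypts, the adenoma against early injury. Crypt base stem cell genes were higher in tumor crypts in 11 of 14 cases (median 1.93, adjusted p = 0.262 with an estimated correlation). Aqp4, chosen after its values were seen, was lower. Lgr5 rose from 33.7 ± 20.4 to 549.6 ± 52.4, a log2 change of 3.52 ± 0.32 (SE, n = 2 and 2, adjusted p = 0.000275). Ascl2 rose from 83.4 ± 2.87 to 489 ± 13.5, a log2 change of 2.32 ± 0.20, and Axin2 by 3.35 ± 0.22, the latter with 1.13 on its other probe set. DNA replication genes were higher in 22 of 25 cases (median 1.62, adjusted p = 0.196 with an estimated correlation). Mcm7 was at 1.90 ± 0.19 and the epigenetic regulator Uhrf1 at 2.16 ± 0.24. Ribosome biogenesis genes were higher in 14 of 23 cases (median 0.80, adjusted p = 0.412 with an estimated correlation). Nop56 was at 1.61 ± 0.19 and Gnl3 at 1.03 ± 0.16, while Utp20, chosen after its values were seen, was lower. The immediate early list did not pass (median -0.42 over 18 genes). Btg2 (-1.17 ± 0.15), Ier2 (-0.86 ± 0.15) and Klf4 (-1.17 ± 0.17) were lower in tumor than in DSS crypts. Ier3 (3.27 ± 0.26), Myc (1.67 ± 0.23), Socs3 and Ier5 were higher. Of these 7, Ier2, Klf4, Socs3 and Ier5 were chosen after their values were seen. Single-gene calls ended without DSS replicate 2 for Utp20 (-0.88) and Ier5 (0.98) (log2 changes). They ended for Utp20 (-0.72) without tumor replicate 1. They ended for Ier5 (0.89) without DSS replicate 1. They ended for Ier5 (0.64) without tumor replicate 2. DNA replication genes, whose median moved by more than 1.5 times in some settings, had a median of 0.99 with a pseudocount at the median. With a pseudocount at the median, the log2 change of Lgr5 was 2.22.

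Wnt target genes were higher than in DSS crypts in 23 of 25 cases (median 2.93, adjusted p = 0.196 with an estimated correlation), and mitosis genes in 19 of 27 (0.96, adjusted p = 0.196 with an estimated correlation). Antimicrobial genes were higher in 10 of 15 (3.66, adjusted p = 0.262 with an estimated correlation) and NF-kB cytokine genes in 9 of 15 (1.24, adjusted p = 0.517 with an estimated correlation). Matrix remodelling genes were higher in 11 of 14 (1.86, adjusted p = 0.335 with an estimated correlation). The largest rises were in Reg3g (7.17 ± 0.47), Apcdd1 (7.07 ± 0.29), Mmp7 (6.97 ± 0.20), Mt4 (6.85 ± 0.18), Wif1 (6.74 ± 0.24), Reg3b (6.65 ± 0.66), Cxcl5 (6.33 ± 0.34) and S100a8 (6.27 ± 0.88). With a pseudocount of 1 and with one at the median of all values, the changes were 8.64 and 5.30 for Reg3g, 7.97 and 5.29 for Apcdd1, 6.92 and 5.68 for Reg3b, 6.95 and 4.84 for Cxcl5 and 7.68 and 4.30 for S100a8, so the order of these genes depends on it. Lower were colonocyte genes in 13 of 19 cases (median -1.58, adjusted p = 0.196 with an estimated correlation) and goblet cell genes in 15 of 20 (-1.11, adjusted p = 0.262 with an estimated correlation). Enteroendocrine genes were lower in 8 of 11 (-1.22, adjusted p = 0.412 with an estimated correlation) and ion transport genes in 11 of 19 (-1.22, adjusted p = 0.196 with an estimated correlation). Xenobiotic metabolism genes were lower in 15 of 23 cases (-1.21, adjusted p = 0.275 with an estimated correlation) and fatty acid oxidation genes in 9 of 17 (-0.72, adjusted p = 0.262 with an estimated correlation). Oxidative phosphorylation genes were lower in 15 of 27 (-0.55, adjusted p = 0.51 with an estimated correlation). Smooth muscle genes fell as a group with 0 of 9 genes past the test (-1.54, adjusted p = 0.61 with an estimated correlation). The largest falls were in Ogn (-4.51 ± 0.41), Mptx1 (-4.46 ± 0.33), Rps4l (-4.32 ± 0.51), Car4 (-4.29 ± 0.51), Aqp8 (-4.26 ± 0.36), Insl5 (-4.04 ± 0.33), Slc37a2 (-4.04 ± 0.29) and Slc26a3 (-3.85 ± 0.35). Genes against the direction of their list, chosen after their values were seen, were Pigr for antimicrobial, Ccl28, Il18 and Birc3 for NF-kB and Emp1 for colonocyte genes. They were Aqp1, Sgk1 and Kcnq1 for ion transport, and Cyp2b10, Txnrd1 and Gsta4 for xenobiotic genes. Isl1 was higher among enteroendocrine genes, and Pdk4 and Acot1 among fatty acid oxidation genes, of which Isl1 and Acot1 were chosen after their values were seen. Single-gene calls ended without DSS replicate 1 for Pigr (-0.48), Il18 (-1.07), Birc3 (-0.44), Aqp1 (0.85), Sgk1 (0.70), Kcnq1 (0.49), Txnrd1 (0.97), Gsta4 (0.65) and Acot1 (1.10) (log2 changes). They ended for Pigr (-0.56), Il18 (-0.81), Birc3 (-0.80), Aqp1 (0.53), Sgk1 (0.99), Kcnq1 (0.49) and Txnrd1 (0.73) without tumor replicate 2. They ended for Ccl28 (-1.24), Aqp1 (0.93), Sgk1 (0.89), Kcnq1 (0.80), Txnrd1 (0.91), Gsta4 (0.88) and Acot1 (0.97) without DSS replicate 2. They ended for Birc3 (-0.65), Kcnq1 (0.64) and Gsta4 (0.76) without control replicate 1. They ended for Birc3 (-0.65), Kcnq1 (0.64) and Gsta4 (0.76) without control replicate 2. They ended for Birc3 (-0.49), Sgk1 (0.60), Gsta4 (0.44) and Acot1 (0.94) without tumor replicate 1. They ended for Aqp1 (0.65), Sgk1 (0.56), Kcnq1 (0.41) and Gsta4 (0.53) with each array centred on its median. Wnt target genes, whose median moved by more than 1.5 times in some settings, had medians of 1.81 without tumor replicate 1 and 1.94 without tumor replicate 2. Colonocyte genes had medians of -0.78 without the filter and -0.85 without tumor replicate 1. Enteroendocrine genes had a median of -0.76 with a pseudocount at the median. Antimicrobial genes had medians of 1.99 without the filter and 2.33 with the 75th percentile filter. Smooth muscle genes had medians of -0.91 with a pseudocount at the median and -2.47 with the arrays of high poly-A controls as a block. Oxidative phosphorylation genes had a median of -0.34 with quantile normalization. Matrix remodelling genes had medians of 1.19 with a pseudocount at the median, 1.21 without tumor replicate 1 and 0.75 without tumor replicate 2. The list call ended for NF-kB genes at a median of 1.20 with the 75th percentile filter. It ended for smooth muscle genes at -1.34 with the 75th percentile filter. With a pseudocount at the median, log2 changes were -2.75 for Rps4l, -0.82 for Ccl28, 1.46 for Cyp2b10, 1.47 for Pdk4 and 0.65 for Acot1. Calls of Pigr (-0.28), Aqp1 (0.76) and Kcnq1 (0.52) also ended with quantile normalization. Without the filter calls ended for Pigr, Birc3, Aqp1, Sgk1, Kcnq1 and Gsta4. Without an intensity trend calls ended for Birc3, Sgk1, Kcnq1 and Gsta4. With the 2 compared groups alone in the fit calls ended for Birc3, Kcnq1 and Gsta4. With all kept probe sets tested calls ended for Sgk1 and Kcnq1.

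In all, limma called 1950 of 7456 genes between tumor and DSS crypts, 1107 higher and 843 lower, of which 1073 changed by at least 1 on the log2 scale, and the groups did not overlap in 66.0% of genes against 33.3% by chance. Adjusted over the list alone, 25 Wnt target, 23 DNA replication, 11 crypt base and 17 ribosome biogenesis genes were higher and 13 colonocyte and 17 goblet cell genes lower. Camera with a preset correlation called 16 lists (8 higher, 8 lower), camera with an estimated correlation 0 and fry 16, of which 14 were also called with the preset. The other 2 were the reserve stem cell (median 0.97, fry adjusted p = 0.00561) and YAP target lists (0.91, 0.00561), which camera called without tumor replicate 2 for the first (1.02) and without DSS replicate 1 (0.71) or 2 (0.72) for the second. The count fell to 903 without DSS replicate 1, 1110 without DSS replicate 2 and 954 without tumor replicate 2. The antimicrobial call ended without tumor replicate 1 (median 0.06) or 2 (1.19), as did the NF-kB call (0.38 and -0.13), and the smooth muscle call ended without control replicate 2 (-1.34), DSS replicate 2 (-0.65) or tumor replicate 1 (-0.99). Without a tumor array, genes high in tumor alone, such as Reg3g and Cxcl5, left the test, since the filter needs 2 arrays. The antimicrobial and NF-kB medians without a tumor array therefore cover fewer genes, and do not show that the tumor arrays disagreed. Without tumor replicate 2 the immediate early list passed as lower (-0.74). With all arrays but other settings, camera also called YAP target genes at 1.01 with quantile normalization, 0.68 with median centring, 0.54 without the filter and 0.74 with the arrays of high poly-A controls as a block.

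**Figure D3:**
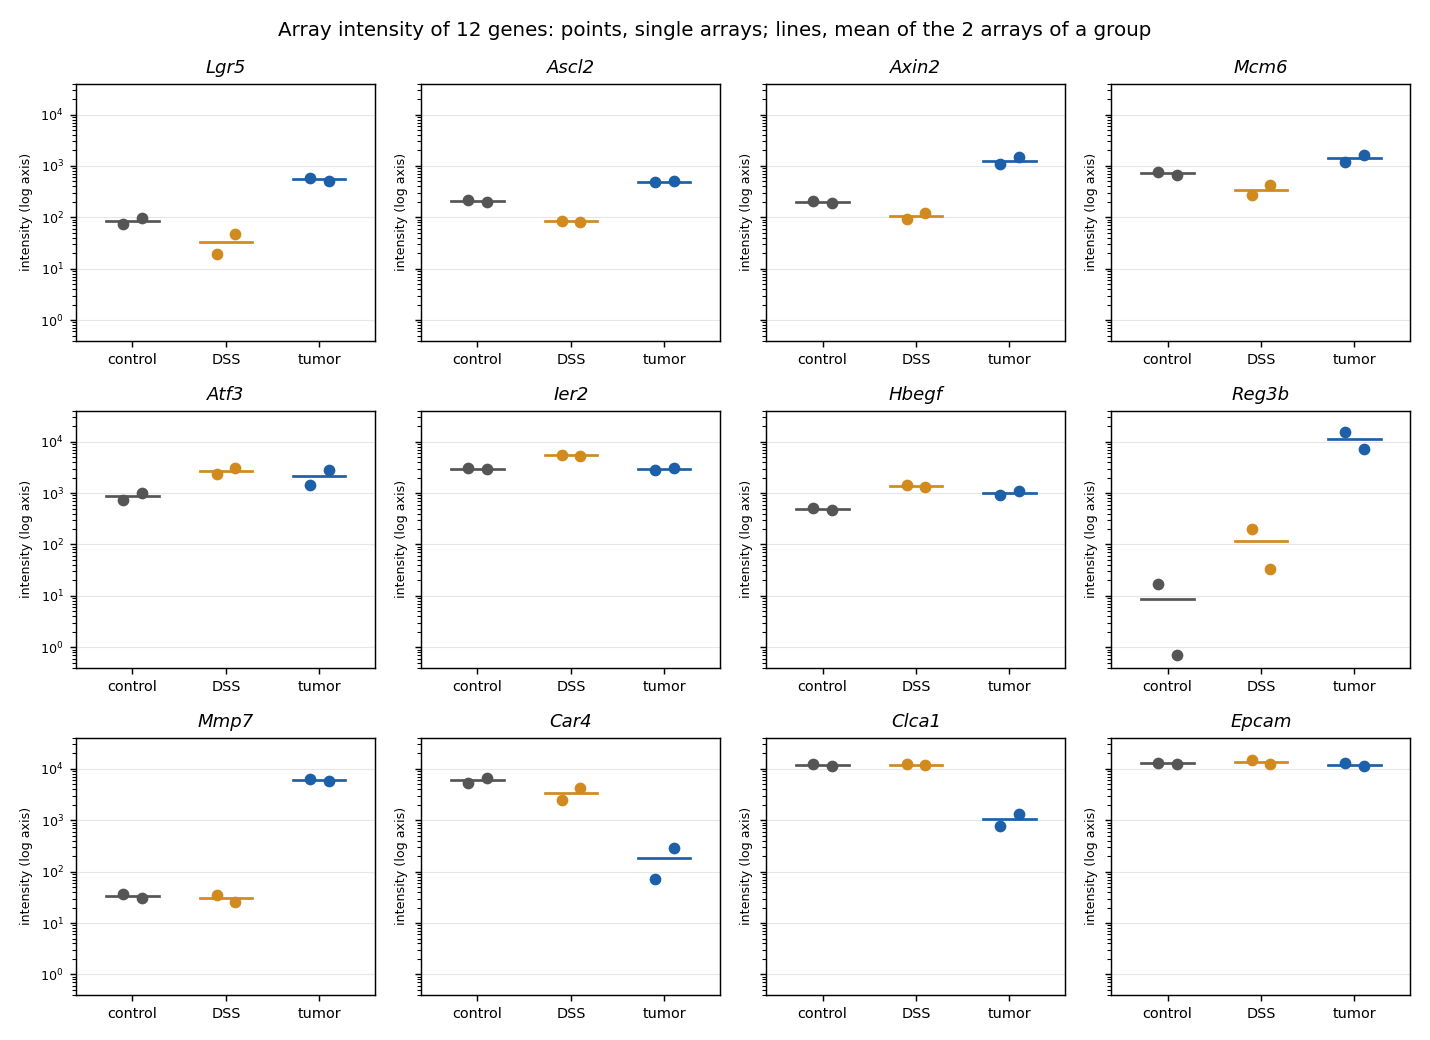
Array intensity on a shared log axis of 12 genes in control, DSS and tumor crypts, with points for single arrays and lines for the mean of the 2 arrays of a group. Lgr5 averaged 85.2 in control, 33.7 in DSS and 549.6 in tumor crypts, while Epcam lay between 12069.9 and 13633 in the group means.

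With camera at a preset correlation, the crypt base, Wnt target, DNA replication and ribosome biogenesis lists were lower in DSS and higher in tumor crypts than in control crypts, and the difference between the treated groups was tested in the third comparison. With an estimated correlation, 0 of these 4 lists passed in either group, and with fry 0 passed in DSS and 3 in tumor crypts, without ribosome biogenesis. Without control replicate 1 the DSS calls ended for Wnt target (-0.05) and ribosome biogenesis genes (-0.06). Immediate early genes had medians of 0.78 in DSS and 0.51 in tumor crypts. With limma 0 genes were called in both against control. Of the 79 genes higher in DSS crypts at an unadjusted p under 0.05, 26 were among the 954 called higher in tumor crypts, where 10.1 would be expected of independent lists, and 12 were among those called lower. Of the 110 lower ones 13 were called lower in tumor crypts, where 10.7 would be expected, and 34 were called higher. Expected counts were not computed for overlaps in the opposite direction. Both comparisons use the same 2 control arrays, which makes their changes correlate on its own: across genes, which are not independent replicates, Pearson's r of the changes was 0.0584, against a mean of 0.502 (SD 0.0173) over 100 simulations of unchanged groups around the same controls. The covariance was 0.0123 against 0.0329 simulated, or 0.0230 with variances from the fit with a replicate block, and 50.8% of genes had the same sign against 66.6%. The simulated arrays were independent and held no tumor changes, whereas large tumor changes can lower r on their own. Same-numbered deviations, which correlated at 0.448 between control and DSS and 0.441 between DSS and tumor, were left out too. The gap to the simulated values therefore decides nothing about changes shared by DSS and tumor crypts. With 2 control arrays the controls cannot be divided into separate sets of 2, and without DSS replicate 2 the correlation was -0.0394, against 0.239 without control replicate 1 and 0.00285 without tumor replicate 2.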

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

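All tests in this part were chosen after the result was seen, except the test of other neutrophil genes. Poly-A spike controls, probe sets outside the comparisons, had a mean intensity of 638 on DSS replicate 1, above the control arrays at 420.3 and 177. No biological explanation was tested for them, and with them as a block the tumor against control count was 1482.

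Immediate early genes were higher in DSS crypts as a list with camera at a preset correlation, but not with an estimated correlation or fry. A difference between batches or handling of the tissue may raise such genes. A batch shared by same-numbered arrays would be balanced between the groups, and a batch that follows the groups was not tested. A handling stress that raised heat shock genes too would need a median like the 0.78 of the immediate early list. Heat shock genes had -0.18 with an SD of 0.449 among members, which argues against that form of it for the list as a set. Its members were mixed, with Dnajb1 at 0.81 and Hsph1 at -1.06, both chosen after their values were seen. A handling difference of both DSS pools that leaves heat shock genes unmoved remains open, as does a response of the crypts to DSS.

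Mgp, Vim, Fn1 and Fbln1 were higher in tumor crypts, and may come from more fibroblasts in the preparations. All 19 tested fibroblast genes had a median change of 0.37 (SD 1.98 among members), and against the control mean it was -0.73 on tumor replicate 1 and 1.37 on tumor replicate 2. Col1a2 measured 89.8 and 961 and Col3a1 307 and 2278 on these arrays. More fibroblasts and a change within the tumor epithelium cannot be told apart here.

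S100a8, S100a9, Lcn2 and Il1b, which neutrophils express and which also stand in the antimicrobial and NF-kB lists, were higher in tumor crypts and may come from neutrophils. The other 9 neutrophil genes, taken without the filter, had a median change of 0.99 (SD 0.937), between 0.5, under which it would have counted against the explanation, and 1, from which it would have counted for it. Of these, 3 averaged above the tumor array median of 121.8: Mmp9 (124), Clec4e (146) and Clec4d (225). S100a9 measured 281 and 4555 and Il1b 187 and 1752 on tumor replicates 1 and 2. Each of the other 9 was also higher on tumor replicate 2, for example Ngp (9.47 and 201), Clec4d (26.0 and 424) and Mmp9 (40.8 and 208). Neutrophils and expression by the tumor epithelium cannot be told apart with these 9 genes, most of which averaged below the tumor array median.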

How the results depend on the processing

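The block for high poly-A controls and the 2-group fit with a replicate block were chosen after the data were seen. In DSS against control, limma called 0 genes (189 at an unadjusted p under 0.05 with all arrays) under the other alternatives, 2 without DSS replicate 1 (Rnase1 and Pnliprp1, chosen after their values were seen), and 124 (53 higher, 71 lower) in the 2-group fit with a replicate block, where 569 had an unadjusted p under 0.05. That fit has 1 residual degree of freedom and an infinite prior, so it rests on pooled variances. Leaving out arrays gave 0 to 2 genes, and 0 to 2 genes shared with tumor crypts in the same direction. The 10 lists called there became 0 with an estimated correlation, 0 with fry, 6 without the filter and 18 in the 2-group fit with a replicate block. The cause was not tested. Camera with an estimated correlation and fry missed most simulated list shifts, but the simulated genes were independent, so this cannot show that the preset calls are right. The labels give same-numbered arrays no shared source, so the numbers were not taken as a pairing. Any variation that same-numbered arrays share therefore stayed in the error of the main fit, which can hide changes in DSS crypts. Same-numbered deviations correlated at 0.448 between control and DSS, 0.0760 between control and tumor and 0.441 between DSS and tumor, so DSS arrays varied together with the same-numbered arrays of either other group. The replicate block alone gave 0 genes and 12 lists.

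In tumor against control, 1680 genes became 967 at a log2 change of at least 1 and 1099 with the 75th percentile filter, where fewer genes were tested, and 702 to 1382 without single arrays. In tumor against DSS, 1950 became 1073, 1260 and 903 to 1923. With an estimated correlation 0 lists were called in either. Inhbb measured -0.12 without the filter, where another probe set is used. Tumor minus control changes had a median of -0.20 with median centring.

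Without single arrays, lists whose called direction or called median changed sign ranged as follows, and the cause was not tested. In DSS against control the medians of the unfolded protein response ranged -0.37 to 0.0718, of fibroblast genes -0.000482 to 0.75, of cholesterol synthesis -0.0704 to 0.45 and of YAP targets -0.0581 to 0.25. In tumor against control fibroblast genes ranged -0.81 to 1.33, and NF-kB genes 0.0075 to 1.60, where the direction given by camera reversed but the median kept its sign. In tumor against DSS NF-kB genes ranged -0.13 to 1.62. Without a tumor array, genes high in tumor alone, such as Cxcl5, left the test, so the NF-kB medians in those settings cover fewer genes. The correlation of DSS and tumor changes was 0.0962 with a pseudocount of 1, 0.0282 with one at the median, 0.115 without the filter and -0.0394 to 0.239 without single arrays, with the cause not tested.

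Of 107 genes named in tumor against control, 73 kept direction and call under every alternative in which they were tested (14 to 17 per gene), as did 34 of 46 in tumor against DSS. Of 33 in DSS against control 27 kept their direction and stayed uncalled in the same settings, which leave out the 2-group fit with a replicate block, where 23 of the 33 were called. Signal over background limits genes of low intensity.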

Other observations

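The gene families and the clock test were chosen after the values were seen. In tumor crypts 6 of 11 tested keratins rose with limma, namely Krt7, Krt18, Krt84, Krt36 (3.69 ± 0.26), Krt23 (3.34 ± 0.24) and Krt14 (3.03 ± 0.28), and with median centring 5 rose without Krt18 and Krt10 fell. Of 5 Sox transcription factors 4 rose under each scaling, namely Sox17 (5.78 ± 0.34), Sox21 (2.84 ± 0.41), Sox4 (2.29 ± 0.17) and Sox9 (1.01 ± 0.23). Of 4 metallothioneins Mt3 (4.34 ± 0.36) and Mt4 (6.46 ± 0.18) rose and Mt1 (-0.81 ± 0.19) fell under each scaling. Other rises were Arg1, an arginase (5.80 ± 0.32), Tnfrsf11b, a decoy receptor (5.43 ± 0.28), and the lipoxygenases Alox12 (4.42 ± 0.31) and Alox15 (3.75 ± 0.40).

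Single arrays differed within groups. Gaps of at least 2 on the log2 scale between replicates occurred in 23 genes of control, 18 of DSS and 61 of tumor crypts. Replicate 2 was the higher one in each group, in 16 of the 23, 15 of the 18 and 60 of the 61. On tumor replicates 1 and 2, the collagen gene Col1a2 measured 89.8 and 961, and the immune genes Tyrobp 83.4 and 627 and Cd74 162 and 999. Matrix remodelling and antimicrobial list genes were among them too, namely Mmp13 (307 and 2226) and Saa3 (301 and 1824). In control crypts the macrophage gene C1qa measured 26.6 and 160 and the smooth muscle gene Tagln 61.0 and 747. In DSS crypts H2-Aa measured 230 and 1210. Whether replicate 2 held more stromal and immune cells, in tumor crypts or in the other groups, was not tested. Retnlb, a goblet cell antimicrobial gene, measured 11923 and 323 on control replicates 1 and 2 and 4655 and 141 on the DSS ones. The immunoglobulin gene Igha measured 668 and 7057 in control, 308 and 8043 in DSS and 393 and 5973 in tumor crypts, and Jchain 186 and 2422, 95.4 and 3094 and 97.5 and 1637. The pancreatic genes Rnase1 and Pnliprp1 measured 1.43 and 1557 and 59.9 and 1837 on the DSS arrays.

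Circadian output genes were lower in tumor crypts: Dbp changed by -2.92 ± 0.33, Tef by -0.94 ± 0.23 and Nr1d2 by -0.67 ± 0.20 with limma, and Nfil3, of opposite phase, by 1.60 ± 0.39. A hypothesis is that tumor crypts were collected at another time of day than control crypts, in which case clock genes of opposite phase should move apart. The 8 evening genes had a median of -0.82 and the 5 opposite ones of 0.77, although Bhlhe40, an evening gene, had 0.69 ± 0.22. Without Dbp, Tef, Nr1d2 and Nfil3, which prompted the hypothesis, the medians were -0.70 for evening and 0.44 for opposite genes. Between the arrays numbered 1 they were then -0.51 and -0.01, and between those numbered 2 -0.36 and 0.98. In DSS crypts all 13 clock genes gave medians of 0.31 and -0.21, which were 0.34 and -0.76 between the arrays numbered 1 and 0.40 and 0.17 between those numbered 2, and limma called 0 of them, with 1 at an unadjusted p under 0.05. Tumor against DSS crypts shares the tumor arrays, and all 13 genes, with those that prompted the hypothesis, gave medians of -1.18 and 1.07. These were -0.98 and 0.63 between the arrays numbered 1 and -1.33 and 1.51 between those numbered 2. There limma called 4 evening genes lower and 2 opposite genes higher. The collection times are not given in the sources used here, and another time of day and a change of the clock in the adenomas cannot be told apart with these genes.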
